A study of Mus musculus with 6 samples.

How the data were processed

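RNA was taken from 6 samples of the MC3T3-E1 cell line, 3 labelled WT and 3 labelled FR. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I, selected for poly(A) with oligo(dT) beads, fragmented, reverse transcribed with random hexamers, amplified by PCR and sequenced as paired-end reads. The labels do not say whether strand was kept, so reads of a gene and of an overlapping antisense gene cannot be told apart here. Per the submitters' processing notes, the reads passed through fastp, HISAT and RSEM with the genome build GRCm39, and no versions, settings or annotation release were given.

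The authors deposited 1 table of expected counts per gene for the 6 libraries, not scaled to depth. It held 54433 genes, of which 733 were assembled loci without a gene name and 53700 carried a name. The values had up to 2 decimals, and 85.9% were whole numbers. The deposited table also held the mean expected counts of each group, which were not used, a gene length, and Gene Ontology and pathway terms. RSEM shares reads that match several genes by estimation, so values of genes with near-identical copies depend on that estimate. The table gives no positions, and the reference annotation at hand is of GRCm38, another build, so no coordinates are given. That annotation served for gene order, gene class and GC content only, and 14333 of 14368 tested Ensembl identifiers (99.8%) were found in it.

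Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 14889 genes, and libraries were scaled with TMM factors. FR was compared with WT by the robust quasi-likelihood F-test of edgeR, without further terms, since no batch is labelled. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05, and a second count required in addition at least a 2-fold change. Log2 fold changes are FR over WT with the standard error of the fit. CPM were computed with the TMM factors and are given as mean ± SD of the 3 libraries of a group. The common biological coefficient of variation was 3.25%. Pairs of libraries of a group differed by 2.34 to 3.37 times the sampling noise (chi-square per degree of freedom, genes with at least 20 counts over the pair), so none is a copy of another, and pairs from different groups by 111 to 133 times. Principal components used log2 CPM with a prior count of 2.

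The 34 gene lists, the tests and the rule for naming genes were fixed before the data were examined. The lists cover bone formation and matrix, osteoclast-regulating factors, stress and cell death, proliferation, energy metabolism, cholesterol synthesis, transport, signalling, interferon and inflammation, and markers of other cell types. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 30 lists, then with an estimated correlation and with fry. Members were counted after adjustment over all genes and over the list alone. Annotation terms with 10 to 300 tested genes were tested by a one-sided hypergeometric test among 13250 tested genes that carry a term, with 898 genes at least 2-fold higher and 1488 at least 2-fold lower. The genes named are the 8 largest rises and 8 largest falls with a mean of at least 5 CPM, no overlap between the groups and a proper symbol. For each main list the 3 members with the smallest adjusted p are named, with the member of smallest adjusted p in the other direction where all 3 agree in sign, and for each other list 1 member. Runx2, Sp7, Alpl, Bglap, Ibsp, Spp1 and Col1a1 are named whatever their values, and up to 3 members of each term described. Of the genes that this rule takes, 3 are not reported here.

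The steps were tested on simulated counts with the means and library sizes of these samples. Of 50 genes changed at each size, edgeR called 58% at 1.2-fold, 66% at 1.5-fold, 86% at 2-fold and 96% at 4-fold among 14657 genes, and 13 of 14457 unchanged genes (0.0899%) were called. In the simulation camera called the 1 list that was shifted and none of the others. Genes were drawn independently there, so the preset correlation was not tested, and the estimated correlation of the real lists reached 0.570. Few simulated genes were changed, against 70.1% called in the data, so scaling and adjustment were not tested at such a share.

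The alternatives tried were median-of-ratios size factors, library size alone, no filter, a stricter filter of a mean of 1 CPM, a fit that is not robust, the replicate number as a block, each library left out, the 10 most abundant genes left out, DESeq2 1.42.0, limma-voom, glmTreat, the other list tests and all changed genes in place of 2-fold genes for the terms. Leaving out assembled loci, thinning the counts to the smallest library and subtracting the median of the 41 neighbouring genes were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.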

Results

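Messenger RNA was measured by RNA sequencing in MC3T3-E1, a mouse osteoblast-like cell line in common use as a model of bone-forming cells. The series title speaks of osteoblasts from fluoride-tolerant mice, while the sample labels describe cells of this line made resistant in culture, and the text follows the sample labels. The series holds 6 libraries. The 3 control libraries (WT) came from wild-type cells in Dulbecco's modified Eagle medium, and the 3 other libraries (FR) came from fluoride-resistant cells. Per the labels' protocols, the FR cells were obtained by continuous exposure to a gradient of 10 ppm fluoride while proliferation was followed with a cell counting assay, and they were resistant to 30 ppm fluoride. The FR samples are described as exposed to a gradient of 30 ppm fluoride, so resistance and exposure to fluoride are not separated by the design. The table summed to about 27140700, 25700500 and 25798600 counts in the WT libraries and to about 19246100, 25185700 and 21201900 in the FR libraries. At these depths 3 counts in a library corresponded to between 0.111 and 0.156 CPM (counts scaled to library size), which covers counting error only.

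The comparison of FR with WT asked which genes are expressed differently in cells that had become resistant to fluoride. Many genes of the extracellular matrix were lower in FR. Postn (ENSMUSG00000027750), which encodes the matrix protein periostin, fell from 222 ± 11.7 CPM in WT to 1.19 ± 0.361 CPM in FR (SD, n = 3 each), a 183-fold difference. Col1a1 (ENSMUSG00000001506), the alpha 1 chain of type I collagen, fell from 5055 ± 95.6 to 635 ± 9.34 CPM (SD, n = 3 each). All 23 tested genes of cholesterol synthesis fell, and 34 of 42 tested interferon-response genes fell. Genes that rose included Agt (ENSMUSG00000031980), which encodes angiotensinogen and went from 0.578 ± 0.309 to 13.1 ± 1.49 CPM, and Cxcl1 (ENSMUSG00000029380), a neutrophil-attracting chemokine that went from 1.69 ± 0.475 to 27.1 ± 2.33 CPM (SD, n = 3 each).

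Of 14889 genes tested with edgeR, 10440 (70.1%) had an adjusted p under 0.05, 5157 of them higher and 5283 lower in FR. A change of at least 2-fold was found for 2801 genes, of which 1102 were higher and 1699 (60.7%) lower. Changes of at least 8-fold were mostly falls, with 546 genes lower and 46 higher. Among these tests, 37 genes had no count in any FR library and 3 had none in any WT library. With their folds computed against 3 counts per library, 525 genes were at least 8-fold lower and 45 at least 8-fold higher. CPM did not overlap between the groups for 10776 genes (72.4%), where chance gives 10%. The first principal component held 86.6% of the variance of log2 CPM and separated WT from FR. Spearman correlations across genes were 0.997 within WT, 0.996 to 0.997 within FR and 0.948 to 0.949 between the groups. The p-values measure the spread between these libraries, and the labels do not say whether the 3 libraries of a group came from separate cultures.

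**Figure D1:**
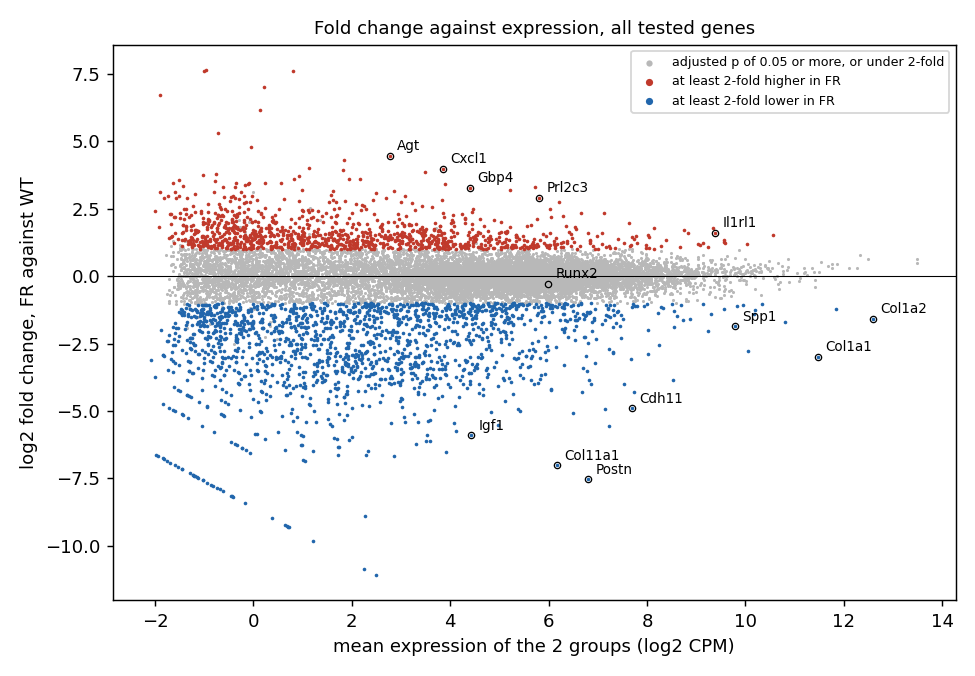
Each point is 1 of the 14889 tested genes, with the mean CPM of both groups on the horizontal axis (log2) and the log2 fold change of FR against WT on the vertical axis. Red points are the 1102 genes at least 2-fold higher and blue points the 1699 genes at least 2-fold lower with an adjusted p under 0.05, and the falls reach farther from 0 than most rises; the diagonal lines of points at the lower left are genes with no count or few counts in FR.

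The 8 largest falls among well-measured named genes were Postn (log2 fold change −7.52 ± 0.09 SE), Col11a1 (−7.01 ± 0.07), Kif26b (−6.51 ± 0.16), Samd12 (−6.48 ± 0.25), Vldlr (−6.21 ± 0.18), Itga11 (−6.12 ± 0.16), Armcx4 (−6.10 ± 0.17) and Igf1 (−5.90 ± 0.12). Col11a1 encodes a chain of a fibrillar collagen, Itga11 a collagen-binding integrin subunit, Vldlr a lipoprotein receptor and Igf1 insulin-like growth factor 1. Igf1 fell from 42.2 ± 3.21 to 0.691 ± 0.180 CPM (SD, n = 3 each). Samd12 was at 0.110 CPM in FR, below the level of 3 counts per library, so its fold change is poorly determined. The largest rises included Agt (4.47 ± 0.20), Cxcl1 (3.98 ± 0.13), Gbp4 (3.28 ± 0.08), Cd209c (3.07 ± 0.16), Cd24a (2.97 ± 0.13), Prl2c3 (2.90 ± 0.05) and Mrgprf (2.81 ± 0.10). Prl2c3, of the prolactin family, rose from 13.2 ± 0.608 to 98.8 ± 4.13 CPM (SD, n = 3 each). The edgeR adjusted p-values of these genes were 2.30e-14 or smaller. Gbp4, Prl2c3 and Cd24a have close paralogues or copies, so the assignment of their reads is uncertain.

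Of the osteoblast lineage and mineralisation list, 22 of 32 genes could be tested, and 4 rose, 16 fell and 2 did not pass. The median log2 fold change was −1.24, and the list was lower than other genes (camera adjusted p = 5.56e-17; adjusted p = 0.0204 with an estimated correlation). Cdh11, a cadherin of osteoblasts, fell from 400 ± 6.98 to 13.5 ± 0.700 CPM (SD, n = 3 each; log2 fold change −4.89 ± 0.04 SE). Col1a2, the alpha 2 chain of type I collagen, fell from 9282 ± 80.5 to 3104 ± 22.4 CPM, and Spp1, which encodes osteopontin, fell from a mean of 1392 to 384 CPM (log2 fold change −1.86 ± 0.04 SE, n = 3 each). Runx2, a transcription factor needed for osteoblast formation, fell from 69.8 ± 1.10 to 57.2 ± 0.694 CPM (log2 fold change −0.29 ± 0.04 SE, adjusted p = 1.67e-07). Smpd3, a neutral sphingomyelinase required for normal mineralisation, rose from 2.57 ± 0.176 to 9.75 ± 0.602 CPM. Sp7, Alpl, Bglap and Ibsp, which mark the maturing and mineralising osteoblast, were near the detection limit in both groups and were not tested. Sp7 had 6, 2 and 8 counts in WT and 0, 2 and 0 in FR, Alpl had 1, 2 and 0 in WT and 0, 1 and 0 in FR, Bglap had 0, 0 and 3 in WT and 0, 2 and 0 in FR, and Ibsp had 0 in every library.

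Of 35 tested genes for fibrillar collagens and collagen assembly, 27 fell, 7 rose and 1 did not pass (median log2 fold change −0.73; camera adjusted p = 1.13e-32; adjusted p = 0.0242 with an estimated correlation). Fmod, named because it had no count in any FR library, was at least 8.11-fold lower against 3 counts per library, and the median was also −0.73 with it at this bound. Col5a2, a chain of type V collagen, fell from 973 ± 25.7 to 238 ± 1.43 CPM, while Loxl1, a collagen and elastin crosslinking enzyme, rose from 126 ± 2.45 to 283 ± 1.40 CPM (SD, n = 3 each). Of 22 tested matrix-degrading enzymes and inhibitors, 16 fell and 4 rose (median −0.41; camera adjusted p = 1.97e-06; adjusted p = 0.141 with an estimated correlation). Both enzymes and inhibitors of this list fell. Timp3, a metalloproteinase inhibitor, fell from 403 ± 12.4 to 20.2 ± 1.04 CPM, the gelatinase gene Mmp2 from 431 ± 9.65 to 167 ± 1.97 CPM and the membrane-bound Mmp16 from 89.5 ± 2.62 to 13.8 ± 1.27 CPM. Adamts7 rose from 11.4 ± 0.880 to 30.7 ± 2.12 CPM (SD, n = 3 each). In the annotation deposited with the table, the term extracellular matrix held 54 genes at least 2-fold lower among 124 tested (hypergeometric adjusted p = 8.73e-17), among them Col8a2 (log2 fold change −5.56 ± 0.05 SE), and the term ossification held 23 of 55 (adjusted p = 3.16e-06), among them Chrdl1, a BMP antagonist.

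**Figure D2:**
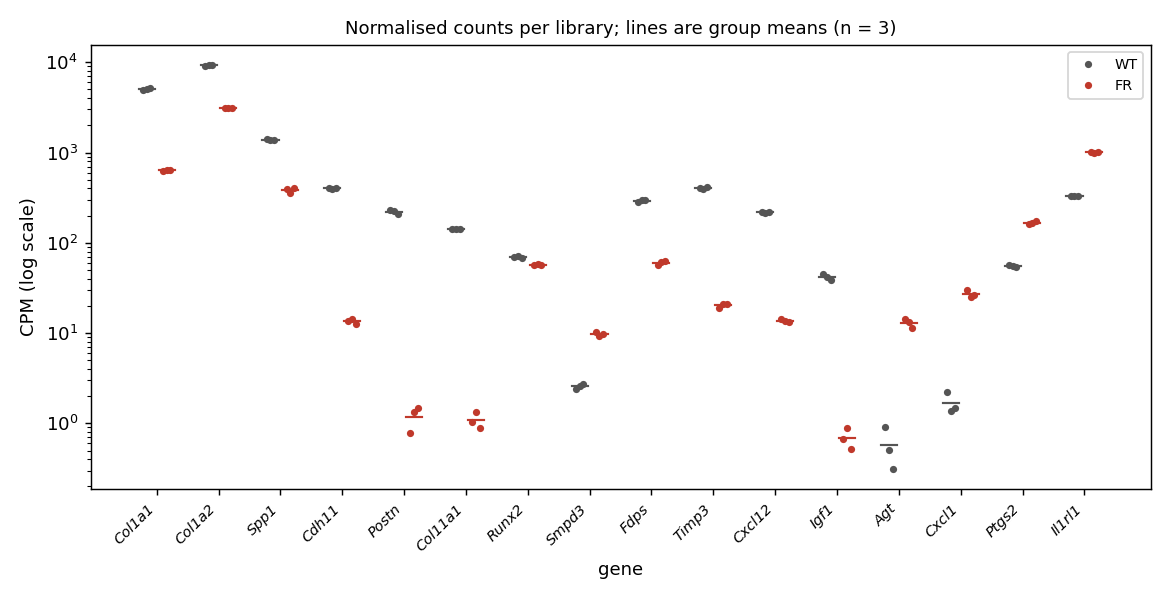
Normalised counts (CPM, log scale) are shown for 16 genes, with 1 point per library, WT in grey and FR in red, and a line at each group's mean (n = 3 each). The libraries of a group lie close together and apart from the other group for every gene shown, with the smallest distance for Runx2 (69.8 CPM in WT and 57.2 CPM in FR).

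Each of the 23 tested cholesterol synthesis genes fell, 21 of them at least 2-fold (median log2 fold change −1.60; camera adjusted p = 1.32e-40; adjusted p = 0.0242 with an estimated correlation). Fdps, which encodes farnesyl diphosphate synthase, fell from 293 ± 6.85 to 60.2 ± 3.04 CPM (SD, n = 3 each). The annotation term cholesterol biosynthetic process held 17 of 26 genes at least 2-fold lower (hypergeometric adjusted p = 5.01e-08). Among them were Hmgcs1, the first committed enzyme of the pathway, at log2 fold change −1.89 ± 0.03 SE, and Cyp51, a sterol demethylase, at −1.45 ± 0.03 SE.

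Of 42 tested interferon-response genes, 34 fell, 4 rose and 4 did not pass, with a median log2 fold change of −1.95 (camera adjusted p = 6.35e-08; adjusted p = 0.185 with an estimated correlation). Oas2, named because it had no count in any FR library, was at least 18.8-fold lower against 3 counts per library, and the median was also −1.95 with it at this bound. Ifi27l2a fell from 41.3 ± 1.94 to 3.92 ± 0.486 CPM and Stat2, a transcription factor of interferon signalling, from 56.6 ± 2.31 to 17.4 ± 1.36 CPM (SD, n = 3 each). The class I histocompatibility gene H2-K1 fell from 35.9 ± 0.239 to 3.98 ± 0.668 CPM and H2-D1 rose from 324 ± 8.57 to 425 ± 5.44 CPM, but these genes are near-identical relatives whose reads can be misassigned. Of 26 tested inflammatory genes of the NF-kB list, 12 rose and 13 fell (median −0.11, mean 0.27, test direction up; camera adjusted p = 0.645). Il1rl1, the receptor for interleukin 33, rose from 330 ± 1.28 to 1009 ± 17.1 CPM (SD, n = 3 each). The term positive regulation of JAK-STAT cascade held 9 of 15 genes at least 2-fold higher (hypergeometric adjusted p = 2.97e-05; adjusted p = 0.190 with all higher genes), among them Cxcl5 (2.75 ± 0.05 SE), Prl2c3 and Prl2c2 (1.79 ± 0.03 SE), of which the Prl2c genes are close paralogues. The term for presentation of endogenous peptide antigen via MHC class Ib held 10 of 25 genes at least 2-fold higher (adjusted p = 0.000397; adjusted p = 0.285 with all higher genes), led by H2-T10, for which the same uncertainty holds.

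Of 11 tested genes for factors that regulate osteoclasts, 5 rose, 5 fell and 1 did not pass. The median was 0.03, the mean −0.75 and the direction of the test down (camera adjusted p = 0.00125; adjusted p = 0.257 with an estimated correlation). Cxcl12, a chemokine for haematopoietic cells, fell from 218 ± 2.63 to 13.8 ± 0.639 CPM and Sema3a, an inhibitor of osteoclast formation, fell from 279 ± 2.60 to 38.2 ± 1.41 CPM. Ptgs2, the inducible cyclooxygenase, rose from 55.1 ± 1.30 to 167 ± 6.62 CPM (SD, n = 3 each).

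Of 27 tested Wnt signalling genes, 17 fell and 6 rose (median log2 fold change −0.48; camera adjusted p = 0.000168; adjusted p = 0.151 with an estimated correlation). Dkk3 fell from 202 ± 10.3 to 17.8 ± 0.360 CPM, the Wnt agonist gene Rspo2 from 27.8 ± 0.521 to 2.19 ± 0.252 CPM and Ccn5 from 45.6 ± 1.03 to 7.09 ± 0.749 CPM, while the ligand gene Wnt5a rose from 38.1 ± 1.25 to 69.4 ± 2.40 CPM (SD, n = 3 each). Of 34 tested BMP and TGF-beta signalling genes, 23 fell and 9 rose (median −0.51; camera adjusted p = 1.07e-05; adjusted p = 0.151 with an estimated correlation). The members with the smallest adjusted p included an inhibitor of transcription, Id4 (log2 fold change −5.09 ± 0.05 SE), the antagonist gene Chrdl1 (−4.31 ± 0.05) and the matrix protein gene Tgfbi (−3.45 ± 0.10), while Id3 rose (0.84 ± 0.04). The term growth factor activity held 23 of 71 genes at least 2-fold lower (hypergeometric adjusted p = 0.000282; adjusted p = 0.395 with all lower genes), among them Ptn (−4.17 ± 0.05 SE), Ccn3 (−3.29 ± 0.05) and Fgf7 (−2.32 ± 0.04). Of 35 tested MAPK feedback and immediate early genes, 9 rose and 19 fell (median −0.13; camera adjusted p = 0.735). Klf4 fell (log2 fold change −2.26 ± 0.05 SE), and Dusp1, a MAPK phosphatase, rose from 16.5 ± 0.825 to 57.4 ± 0.536 CPM, as did the AP-1 gene Fosl2 from 188 ± 2.83 to 380 ± 3.54 CPM (SD, n = 3 each).

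Of 41 tested mitotic cell cycle genes, 26 fell, 9 rose and 6 did not pass, with a median log2 fold change of −0.23 (camera adjusted p = 0.0448; adjusted p = 0.183 with an estimated correlation). This call ended with assembled loci left out (adjusted p = 0.0533) and with a stricter expression filter (adjusted p = 0.0645). The D-type cyclin gene Ccnd1 fell from 703 ± 11.6 to 234 ± 6.30 CPM and Ccnd2 from 316 ± 9.08 to 167 ± 4.41 CPM. The cyclin-dependent kinase inhibitor gene Cdkn1b also fell, from 99.6 ± 2.66 to 59.9 ± 2.86 CPM, and another, Cdkn2c, rose from 161 ± 2.74 to 229 ± 2.64 CPM (SD, n = 3 each). Of 37 tested DNA replication genes 15 rose and 13 fell (median 0.02; camera adjusted p = 0.419), with Rpa1 at log2 fold change 0.71 ± 0.03 SE. Of 8 tested replication-dependent histone genes 3 fell, H2bc4 among them (−1.29 ± 0.20 SE), and none rose (median −0.44; camera adjusted p = 0.796). H2bc4 was low (mean 3.75 CPM in WT and 1.53 CPM in FR) and the RNA was selected for poly(A), so this list is not read as a measure of proliferation.

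Of 36 tested apoptosis genes and p53 targets, 23 fell and 10 rose (median log2 fold change −0.35; camera adjusted p = 0.0529; fry adjusted p = 2.67e-05, down), a list that did not pass with camera. Tnfaip3 fell from 46.6 ± 1.11 to 13.7 ± 0.829 CPM, the p53 targets Phlda3 from 130 ± 5.50 to 68.9 ± 1.83 CPM and Cdkn1a from 138 ± 3.53 to 81.6 ± 1.82 CPM, and Casp12 rose from 33.6 ± 1.34 to 68.7 ± 3.28 CPM (SD, n = 3 each). Camera called no stress list, while fry called 2 of the 4. For the unfolded protein and integrated stress response 15 of 40 genes rose and 22 fell (median −0.14; camera adjusted p = 0.735; fry adjusted p = 0.00261, down). The chaperone gene Hyou1 rose (0.59 ± 0.03 SE), while the cystathionine gamma-lyase gene Cth (−1.45 ± 0.07) and the cystine transporter gene Slc7a11 (−1.84 ± 0.10) fell. For oxidative stress and glutathione 20 of 39 genes rose and 14 fell (median 0.11, mean −0.11, test direction up; camera adjusted p = 0.758; fry adjusted p = 0.695). Gsta4, a glutathione transferase, rose (1.21 ± 0.04 SE), whereas Gpx1, a glutathione peroxidase (−1.08 ± 0.04), and Mt2, a metallothionein (−0.93 ± 0.03), fell. Of 15 heat shock genes 8 rose and 6 fell (median 0.10; camera adjusted p = 0.735; fry adjusted p = 0.0602), with Cryab at −1.18 ± 0.05 SE. Of 19 hypoxia response genes 10 rose and 7 fell (median 0.13, mean −0.16, test direction up; camera adjusted p = 0.692; fry adjusted p = 0.00340, up), with P4ha1 at −0.72 ± 0.03 SE.

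Of 41 tested ion pumps, exchangers and anion channels, 13 rose, 18 fell and 10 did not pass (median log2 fold change 0.01, mean −0.34, test direction up; camera adjusted p = 0.910). The sulfate transporter gene Slc26a2 fell from 84.3 ± 1.84 to 21.5 ± 0.579 CPM, and the sodium-calcium exchanger gene Slc8a1 fell from 7.08 ± 0.425 to 0.320 ± 0.184 CPM (SD, n = 3 each). The term ion channel activity held 23 of 55 genes at least 2-fold lower (hypergeometric adjusted p = 3.16e-06; adjusted p = 0.235 with all lower genes), including the sodium channel gene Scn3a (−2.94 ± 0.06 SE), the calcium channel gene Cacna1g (−4.46 ± 0.11) and the glutamate receptor gene Gria3 (−4.19 ± 0.10). Of 23 tested ABC and drug-efflux transporters 8 rose and 10 fell (median −0.15; camera adjusted p = 0.735). Abca9 (−5.46 ± 0.13 SE) and Abcg2, a drug-efflux pump (−2.87 ± 0.07), fell, and Abca2 rose (0.80 ± 0.03). Of 34 tested genes of the vacuolar ATPase and lysosome 21 fell and 5 rose (median −0.27; camera adjusted p = 0.0387; adjusted p = 0.489 with an estimated correlation), and this call ended with a stricter expression filter (adjusted p = 0.0572).

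Camera called no list for energy metabolism, while fry called the 3 tested. Of 44 nuclear-encoded oxidative phosphorylation genes 23 rose and 9 fell (median log2 fold change 0.13; camera adjusted p = 0.0619; fry adjusted p = 0.00726, up), with Uqcrc1 at 0.55 ± 0.03 SE. Of 13 mitochondrially encoded proteins 7 rose and 6 did not pass (median 0.27; camera adjusted p = 0.0827; fry adjusted p = 0.00421, up), with mt-Co1 at 0.64 ± 0.03 SE. Genes with names that start with mt- took 2.63 ± 0.0103% of counts in WT and 3.45 ± 0.139% in FR (SD, n = 3 each). Any copies of them under other names are outside this share, and reads can be shared with such copies, so these values are uncertain. Of 25 glycolysis and lactate genes 7 rose and 9 fell (median 0.03, mean −0.07, test direction down; camera adjusted p = 0.735; fry adjusted p = 0.00421, down). Gapdh fell from 1730 ± 29.3 to 840 ± 5.49 CPM, Eno1 from 931 ± 23.9 to 576 ± 16.2 CPM and Pfkp from 77.2 ± 2.29 to 37.2 ± 1.01 CPM, and Ldhb rose from 29.7 ± 0.850 to 55.1 ± 0.116 CPM (SD, n = 3 each). Gapdh and Eno1 have processed copies in the genome, so their values are uncertain. Of 46 ribosomal protein genes 35 rose and 6 fell (median 0.22; camera adjusted p = 0.0529). Rps18 fell from 514 ± 18.8 to 88.5 ± 1.61 CPM, and its count is uncertain, since reads can be shared with its processed copies. Of 21 YAP and SRF target genes 8 rose and 12 fell (median −0.24; camera adjusted p = 0.0953). Acta2, smooth-muscle actin, fell from 586 ± 3.80 to 160 ± 1.31 CPM (SD, n = 3 each).

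Of 5 tested macrophage and leukocyte markers 2 rose and 2 fell (median −0.09, mean 0.24, test direction up; camera adjusted p = 0.849), and Csf1r had a mean of 0.587 CPM in WT and 7.14 CPM in FR (log2 fold change 3.59 ± 0.21 SE). Of 5 osteocyte markers 4 fell, Pdpn among them (−1.02 ± 0.04 SE; camera adjusted p = 0.0111; adjusted p = 0.156 with an estimated correlation). Of 6 tendon and smooth-muscle markers 5 fell and 1 rose (camera adjusted p = 0.00750; adjusted p = 0.151 with an estimated correlation), with Acta2 the member of smallest adjusted p. Of 5 chondrocyte markers 3 fell, Sox9 among them (−0.51 ± 0.04 SE; camera adjusted p = 0.645). Lists with fewer than 5 tested genes were only counted. Of 3 adipocyte markers 1 rose and 2 fell, Lpl among them (−1.69 ± 0.48 SE), of 2 skeletal muscle markers 1 rose, Des (1.82 ± 0.16), and 1 fell, and of 3 endothelial markers 1 rose, 1 fell and 1 did not pass, with Emcn lower (−1.16 ± 0.22). The only tested epithelial marker, Cdh1, was 0.583 ± 0.0663 CPM in WT and 0.302 ± 0.244 CPM in FR (edgeR adjusted p = 0.0711).

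**Figure D3:**
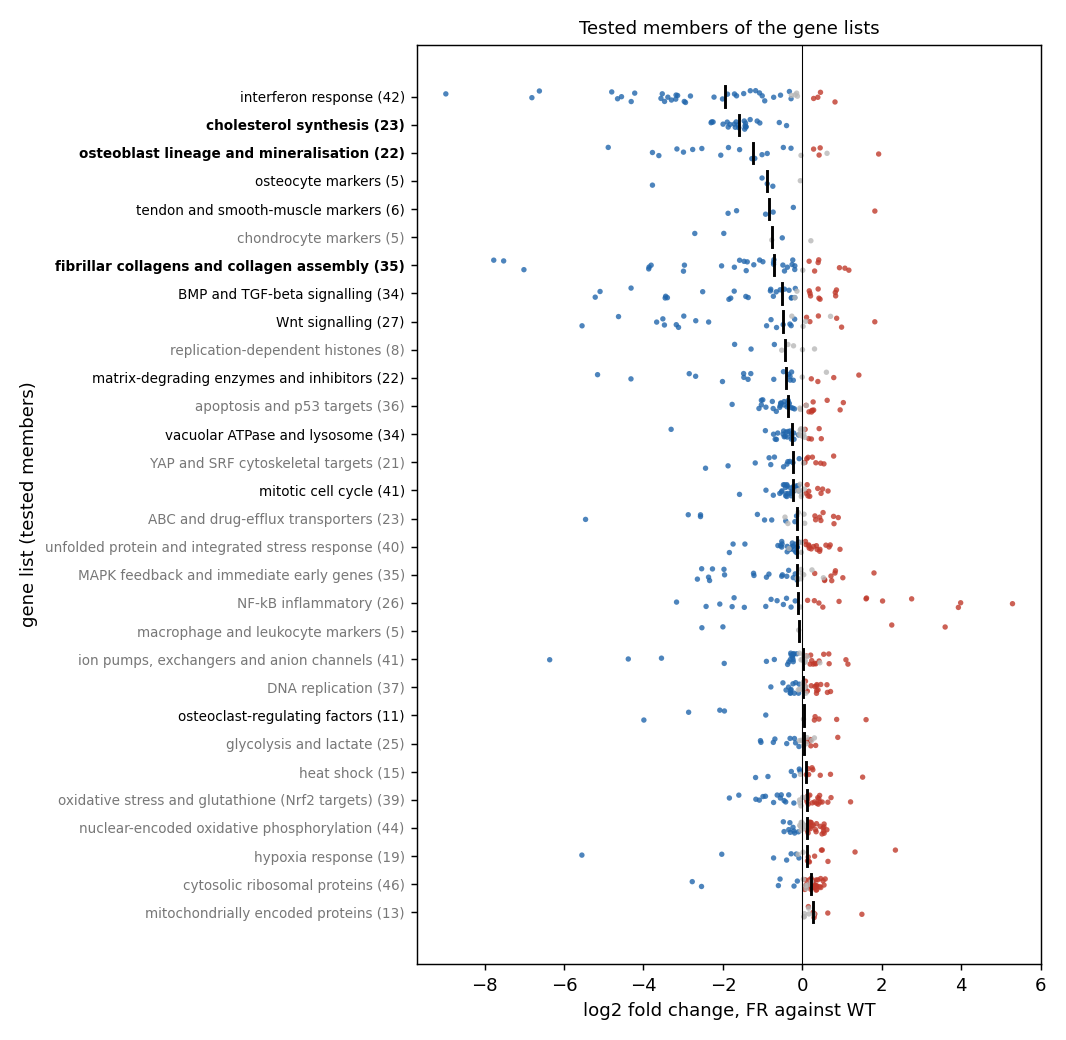
The log2 fold changes of FR against WT are shown for the tested members of the 30 gene lists, 1 point per gene, red if higher and blue if lower with an adjusted p under 0.05 and grey otherwise, with black bars at the medians and the number of tested members in brackets. Names in black are the 12 lists called by camera and those in bold the 3 called also with an estimated correlation, and the medians run from −1.95 for the interferon response to 0.27 for mitochondrially encoded proteins.

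Of the 34 lists, 30 had at least 5 tested genes, and camera called 12 of them, all with the test direction down. Among these 12, the list of osteoclast-regulating factors had 5 genes higher, 5 lower and a median log2 fold change of 0.03. With an estimated correlation 3 remained called, those for the osteoblast lineage, fibrillar collagens and cholesterol synthesis, while fry, which asks whether a list's genes move on balance one way, called 26 (21 lower, 5 higher). Adjusted over the list alone, the counts of higher and lower genes equalled those above except for 27 falls in the mitotic cell cycle list, 10 rises in the MAPK list, 11 falls in the ABC transporter list and 6 rises among mitochondrially encoded proteins. Of 2950 annotation terms tested, 48 were called among genes at least 2-fold higher and 119 among genes at least 2-fold lower. The term with the smallest adjusted p among higher genes, DNA integration (60 of 201 genes, hypergeometric adjusted p = 4.69e-20), consisted largely of assembled loci without a gene name. Without these loci it held 11 of 55 genes (adjusted p = 0.0193), and the term viral process went from 64 of 228 genes (adjusted p = 4.69e-20) to 10 of 86 (adjusted p = 0.355). Assembled loci took 0.921 ± 0.0346% of counts in WT and 1.44 ± 0.0446% in FR (SD, n = 3 each), and of the 521 tested 337 were higher and 67 lower in FR.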

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

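The alternatives with assembled loci left out, with thinned counts and with the neighbourhood median subtracted were chosen after seeing the data. Over 17 alternatives between 9317 (DESeq2) and 10931 (no filter) genes were changed. Over 19 alternatives the genes changed at least 2-fold ranged from 1177 to 3516. The lowest value, 1177, subtracts the median of the 41 neighbouring genes, which exists for 10905 genes, and 1294 of those were changed 2-fold before and 1090 both before and after, so most of the fall comes from fewer genes tested. Next were 1882 with glmTreat, which tests against the 2-fold threshold itself, and 2110 with the stricter filter, which tests fewer genes. Leaving out each library in turn gave 9968 to 10221 changed genes and 2890 to 2956 changed 2-fold. With the replicate number as a block there were 10292 and 2787, and with thinned counts 10076 and 2633.

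Camera called 12 lists, an estimated correlation 3 and fry 26, and leaving out each library in turn gave 13 to 15. Fry asks another question than camera, since it does not compare a list with other genes. With an estimated correlation camera also uses the residual degrees of freedom of the 6 libraries, where with the preset one it uses those of all genes. That by itself raises p-values, so a call lost there need not mean that the genes of a list are correlated. The osteoblast lineage list had an estimated correlation of −0.00234, below the preset 0.01, and its unadjusted camera p still went from 5.56e-18 to 0.000681. Counted over lists and alternatives, a call was gained in the same direction 29 times and lost 12 times, 9 of the 12 with the estimated correlation. The other 376 comparisons were counted as unchanged, but these include uncalled lists whose direction turned. The ion pump list, for example, was up with camera (adjusted p = 0.910) and called down with fry (adjusted p = 0.0129). Terms numbered 168 without assembled loci and 176 with all changed genes, of which only 45 were also called with 2-fold genes. Named genes kept their call in 2638 comparisons with alternatives and none reversed. Only Cdh1 gained a call, with limma-voom and without FR replicate 1 (log2 fold change −1.74), where its log2 fold change ranged from −1.74 to −0.58 over 15 alternatives, and the cause was not tested. Scaling with median-of-ratios size factors or library size alone moved the median log2 fold change of all genes from 0.0029 to 0.0007 and −0.0017. Genes such as Alpl, Bglap and Ibsp, with at most 3 counts in a library, were hardly or not detected in either group, so no change in them can be judged.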

Other observations

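The gene groups of this and the next paragraph were put together after the values were seen, so their tests (camera, adjusted over 3 groups) only describe these libraries. HOX genes, which mark position along the body axis, were mostly higher in FR. Of 19 tested, 17 rose, 1 fell (Hoxa10, 2.45 to 0.299 CPM) and 1 did not pass (Hoxd3), with a median log2 fold change of 1.15 (adjusted p = 0.000331; adjusted p = 0.0239 with an estimated correlation). Hoxa7 rose from 30.6 ± 1.95 to 64.1 ± 0.430 CPM, Hoxb6 from 20.1 ± 0.587 to 48.6 ± 2.17 CPM and Hoxc6 from 2.35 ± 0.144 to 7.92 ± 1.09 CPM (SD, n = 3 each). Transcription factors known from the development of the skull and face went the other way, with 16 of 23 lower and 5 higher and a median of −2.32 (adjusted p = 7.09e-15; adjusted p = 0.00773 with an estimated correlation). Tfap2b fell from 126 ± 2.78 to 6.71 ± 0.275 CPM, Six2 from a mean of 113 to 9.06 CPM (log2 fold change −3.64 ± 0.06 SE) and Alx1 from 82.6 ± 3.80 to 6.06 ± 0.0840 CPM, while Twist2 rose from 20.2 ± 0.975 to 35.3 ± 1.96 CPM (SD, n = 3 each).

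Imprinted genes moved in both directions. Of 23 tested, 10 rose, 11 fell and 2 did not pass (median log2 fold change −0.04; adjusted p = 0.502). Sgce fell from 13.6 ± 0.769 to 0.303 ± 0.0382 CPM and Peg13 from 17.3 ± 1.34 to 2.18 ± 0.145 CPM, while Peg3 rose from 21.1 ± 1.46 to 78.9 ± 2.93 CPM and Slc38a4 from 38.6 ± 1.86 to 85.2 ± 0.673 CPM (SD, n = 3 each).

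Of the tests in the paragraphs that follow, those for local co-regulation or reads shared by adjacent genes, for reads shared with ribosomal copies, for genomic DNA and for reads moved between listed copies were chosen only after the result was seen. Neighbouring genes moved together: over 10905 genes in GRCm38 order, ranked fold changes of genes 100 places apart correlated at 0.0740 (SD 0.0182 over chromosome resamples; 1000 shuffled orders reached at most 0.0283), adjacent genes at 0.205 (at most 0.0324 when shuffled), and 17 stretches of at least 50 genes, 7 higher and 10 lower, held 1707 genes, against at most 1 stretch in 100 shuffled orders. The longest, from Svep1 to A930004J17Rik, held 286 genes with 198 higher and 45 lower, and that from Atp7a to Erdr1 had a median log2 fold change of −0.81. The 100 orders shuffled single genes and so removed the correlation of adjacent genes, and the count of stretches therefore cannot tell them from local co-regulation. After trends with GC content, gene length and expression were removed the correlation was 0.0734, which argues against these trends as the cause, and differences between libraries of 1 group reached at most 0.0201 where those between groups were at least 0.0655. Local co-regulation or reads shared by adjacent genes may account for the excess of the adjacent over the distant correlation, 0.131 (SD 0.0239), and stay open for the distant one, since orders with blocks of 5, 10 or 20 adjacent genes shuffled whole (1000 each) reached at most 0.0446, which is below 0.0740 by less than 2 SD. A change in DNA copy number of chromosome segments may account for such stretches, and so may an origin of the FR cells in another subclone or line, but the table holds no DNA or allele data and both stay open and untested; with another origin, the HOX and craniofacial values and the fold changes of FR against WT in general would include differences between lines and not only those of resistance.

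In 8 of 30 families a ribosomal protein gene fell while a processed copy rose. Rps2 went from 1858 to 272 CPM and Rps2-ps10 from 773 to 2249 CPM, while the family sum went from 3081 ± 112 to 3594 ± 151 CPM (SD, n = 3 each). These families were chosen because the parent fell and a copy rose, which by itself pulls their sums towards 0, so the copies were also reassigned among the same 8 parents. The mean absolute log2 fold change of the sums was 0.166 with each parent's own copies, and 3 of 1000 reassignments were as low (median 0.66). Reads shared between a gene and its copies remain a candidate explanation, so the falls of Rps2 and Rps18 are uncertain, and why the sharing would differ between the groups was not tested.

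Assembled loci whose annotation matches retroviral proteins or reverse transcriptase domains, called retroviral loci below, were higher in FR. Of 222 tested, 168 were higher and 20 lower, with a median log2 fold change of 0.92. Reverse transcriptase domains are not particular to retroviruses, so the set may hold other mobile elements. Genomic DNA or unspliced RNA was checked in 5 noncoding gene classes. Their highest median was 0.330 (processed pseudogenes, 95% bootstrap interval 0.250 to 0.403), under that of the retroviral loci. Retroviral loci can collect reads from many genomic copies, unlike most genes of these classes, so this check cannot exclude it as the whole cause. It also stays open as a part of the cause, since long intergenic RNAs rose (0.224) while antisense genes (−0.0244) stayed near protein-coding genes (−0.0241). Reads moved between listed copies are argued against. The summed counts of 279 such loci went from 7135 ± 282 to 11682 ± 377 CPM (SD, n = 3 each), and the lowest log2 ratio over 9 pairs of libraries was 0.611. Assembly of loci from reads that favoured FR may account for part of the rise, since assembled loci without a retroviral match also had a median of 0.696. Activity of endogenous retroviruses, or of other mobile elements in the set, in the resistant cells stays open, and was not tested apart from this.

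Of the 10 ways to split the 6 libraries 3 against 3, 1 gave as many changed genes as the real one, namely the real split itself. The real split gave 10440 changed genes, 2801 genes changed 2-fold and 12 lists, and the highest of the other splits gave 0, 0 and 11. Each other split holds libraries of both groups on both sides, so the difference between WT and FR adds to the spread within a side. Its 0 changed genes therefore do not measure chance. Camera called 3 to 11 lists in these splits, so the count of 12 lists does not set the real split apart. With 10 splits the share cannot be under 0.05.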
